A study of Homo sapiens with 4 samples.

How the data were processed

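Messenger RNA levels were measured on microarrays in Huh7 cells, a human hepatocellular carcinoma cell line. The cells had been treated with a small interfering RNA (siRNA) against nuclear factor 90 (NF90), a protein that binds double-stranded RNA, or with a control siRNA that the labels call siNTC. There were 2 arrays of siNTC cells and 2 of siNF90 cells, and each group was taken from the sample titles. Nothing in the labels says whether the replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

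Per the labels, total RNA was isolated with a column kit, amplified, and converted to fragmented, biotin-labelled single-stranded cDNA with Affymetrix kits. Per the labels, the authors made the deposited values with the RMA-sketch method in Affymetrix Expression Console, and these are on a log2 scale. RMA corrects the background, normalizes quantiles and summarises the probes of each probe set. The labels do not state the log base, which was taken from the method and from the range of the values. The version of that program and the genome build are not given in the sources used here. The table held 352859 rows on 4 arrays. Each row is a probe set that covers part of a gene, so most genes had several rows. The platform's probe table paired 257971 rows with 1 gene symbol and 17460 rows with several, and 77428 rows were unnamed. Only rows with 1 symbol were used. The symbols are those of the platform's table and can be old. The gene that encodes NF90 is not reported here, so the depletion was not checked and the labels were taken as given.

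Gene values were computed as follows, by choices made before the data were examined. Rows whose mean over all 4 arrays was below the 40th percentile of all rows, a log2 value of 2.13, were left out as dim. The value of a gene on an array was the mean of its remaining rows. This gave 171120 rows in 19140 genes, with a median of 7 rows per gene. A difference is always siNF90 minus siNTC on the log2 scale. A mean over rows that includes weakly responding probe sets, and RMA itself, both pull folds towards 1, so the fold of a named gene depends on the dim filter and on the summary of rows. The precision is limited by the number of arrays, which is 2 per group.

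The main test was limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes on gene values, a two-sided moderated test, no covariate, and Benjamini-Hochberg adjustment over all genes at a threshold of 0.05. Standard errors (SE) are those of this fit, except under the other observations, where those of genes called with the trend and robust prior come from that fit. Before the files were opened, 35 gene lists with 913 different genes were also fixed. Of those genes, 819 were named in the probe table, directly or through an older symbol in the RefSeq gene table, and 804 were tested. Lists were tested with limma's camera against all other genes with its preset inter-gene correlation of 0.01, adjusted over the 35 lists. Beside each call in the main setting the adjusted p with an estimated correlation is printed, and fry was run as well. With that estimate camera tests on the few residual degrees of freedom of the 4 arrays. All 35 lists then had an adjusted p of 0.93, so a lost call need not reflect correlation. The median of each list was also ranked among 10000 random lists of the same size matched on mean level in 20 bins. Such random lists do not carry the correlation among a list's own members. Single rows were tested with limma, and unequal change of the rows of a gene with limma's diffSplice (Simes method).

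The genes named in the text were chosen by a rule. It takes EGFR, CCNE1 and ILF2. It then takes, in each direction, the 12 genes past the threshold with the largest difference, filled up with the smallest unadjusted p where fewer passed. Both siNF90 arrays had to lie beyond both siNTC arrays, and the gene needed at least 3 kept rows. For each list described, the rule takes up to 4 members past the threshold, or the 2 with the smallest p where none passed. For unequal probe sets it takes the 5 genes with the smallest false discovery rate. Further members named for a list were chosen after their values were seen.

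The alternatives fixed beforehand were no dim filter, a filter at the 60th percentile, the median of rows, at least 50% of a gene's rows above the filter, quantile normalization again, centring of each array on its median, eBayes with a trend and robust prior, the replicate number as a block, and leaving out each array in turn. Over all genes the replicate numbers showed no pairing of the arrays, since the deviations of same-numbered arrays from their group means correlated at -0.0118. Alternatives added after seeing the data were genes with at least 3 rows only, identical rows counted once, removal of a smooth trend on the mean level, and a test of rows on each row's own spread. The second of these was added because 6958 kept rows in 199 genes repeat the values of another row of the same gene.

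The scripts were tested on simulated data with the spread estimated from these arrays, over 19140 genes. For the comparison of siNF90 with siNTC, the main test called 0 of 100 genes changed by 2 log2 units and 0 of 100 changed by 1, with 0 false calls. The trend and robust prior also called 0 of 100 and 0 of 100, with 0 false calls. The simulated spread did not vary with a gene's mean level, so these counts need not hold for that prior on the real arrays. With the spread divided by 5, the main test called 99 of 100 and 97 of 100, with 16 false calls. Camera called the 1 list that had been shifted by 0.3 and 0 others. The simulated genes varied independently, so this does not show how often camera falsely calls lists of correlated genes. DiffSplice, simulated over 16175 genes, called 34 of 50 changed genes and also 1839 unchanged ones. Its count in the main setting is therefore given beside the counts from other groupings of the arrays. No such counts were made for the alternative settings.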

Results

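The data set compared Huh7 cells depleted of NF90 with Huh7 cells that had received a control siRNA. Huh7 is a human hepatocellular carcinoma line, and NF90 is a protein that binds double-stranded RNA and has been reported to hold back the maturation of microRNA-7 (miR-7). Total RNA from 2 siNTC and 2 siNF90 samples was hybridised to 1 array each. The medians of all 352859 probe sets lay between 2.72 and 2.79 on the log2 scale on the 4 arrays. Over the 19140 genes tested, the arrays correlated at between 0.936 and 0.958 (Pearson's r across genes, which are not independent replicates). The siNTC arrays correlated with each other at 0.957 and the siNF90 arrays at 0.950. The closest pair was the first siNTC and the first siNF90 array, at 0.958. The second siNF90 array stood farthest from the rest, with r = 0.943 and 0.936 to the siNTC arrays.

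The first question was how the genes tied to NF90 in liver cancer cells behaved. ILF2, which encodes NF45, the partner protein of NF90, had a gene value of 8.31 ± 0.062 (SD, n = 2) in siNTC and 8.26 ± 0.11 (SD, n = 2) in siNF90 cells. Its difference of -0.047 (SE 0.18) had a 95% interval from -0.52 to 0.42 and an adjusted p of 0.954 in limma, and 12 of its 15 probe sets were higher in siNF90. EGFR, the epidermal growth factor receptor and a reported miR-7 target, had 6.36 ± 0.14 in siNTC and 6.50 ± 0.076 in siNF90 cells (SD, n = 2 each). The EGFR difference of 0.15 (SE 0.18) had a 95% interval from -0.34 to 0.63 and an adjusted p of 0.842 in limma. CCNE1, which encodes the G1/S cyclin E1, had 5.55 ± 0.15 and 5.44 ± 0.44 (SD, n = 2 each), a difference of -0.11 (SE 0.27) with an interval from -0.82 to 0.60 and an adjusted p of 0.926. Each of the 3 differences was smaller than its SE. The sign of the CCNE1 difference turned to 0.20 without the second siNF90 array. The ILF2 difference also changed sign, to 0.028 without the second siNF90 array and to between 0.0055 and 0.20 without the dim filter, with the stricter filter, with the median of rows or with quantile normalization again. The gene that encodes NF90 is not analysed here.

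Across all genes, the main limma test called 0 of 19140 genes at an adjusted p of 0.05, and the smallest adjusted p was 0.514. At an unadjusted p under 0.05 there were 1683 genes, 671 higher and 1012 lower in siNF90, where 957 would be expected by chance. With a trend and robust prior, an alternative fixed beforehand, limma called 48 genes, 22 higher and 26 lower in siNF90, of which 34 differed at least 2-fold. Counted without a test, 194 genes with at least 3 probe sets differed at least 2-fold with both siNF90 arrays beyond both siNTC arrays, 85 higher and 109 lower. The other 2 ways of splitting the 4 arrays into pairs gave 72 and 87 such genes. Over genes with any number of probe sets the count was 455, against 339 and 347 in the other splits. Those splits gave 0 calls each with the trend and robust prior. With 3 splits in all, no share under 0.05 is possible. The splits are not independent references, since a gene without overlap in the real split has overlap in the others. The other splits also mix the groups, so any siNF90 effect widens their spread and can lower their calls. Of the 19140 genes, 41.1% had no overlap between the groups, where chance gives 33.3%.

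Among the genes higher in siNF90 cells, CYP24A1, the vitamin D 24-hydroxylase, had the largest difference of the 12 genes with the smallest p. Its value was 4.98 ± 0.39 in siNTC and 7.52 ± 0.073 in siNF90 cells (SD, n = 2 each), which is 5.79-fold. All 14 of its probe sets were higher in siNF90. SLC16A6, a member of the monocarboxylate transporter family, was 4.18-fold higher, with 3.93 ± 0.20 against 5.99 ± 0.082 (SD, n = 2 each). NR0B2, the nuclear receptor SHP that represses bile acid synthesis, was 3.13-fold higher. CYR61, a secreted matrix-associated protein, was 3.07-fold and IGFBP4, a binding protein of insulin-like growth factors, 3.01-fold higher. The transporter SLC16A4 had a low level of 2.65 ± 0.14 (SD, n = 2) in siNTC cells and lay at 3.99 and 4.02 on the siNF90 arrays. The actin-binding TAGLN was 2.44-fold, the phospholipase LIPH 2.38-fold and the granzyme B inhibitor SERPINB9 2.37-fold higher. The remaining genes were TNRC6C-AS1 at 2.33-fold, SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, at 2.28-fold, and the membrane scaffold MPP1 at 2.23-fold. Whether the probe sets of TNRC6C-AS1, an antisense transcript, are free of signal from the opposite strand is not given in the sources used here. In the main limma test each had an adjusted p of 0.514. With the trend and robust prior 7 of the 12 passed the threshold. They were CYP24A1 (adjusted p = 0.0041), SLC16A6, CYR61 and NR0B2 (each 0.0085), IGFBP4 (0.012), SPRY4 (0.012) and SERPINB9 (0.021). Not all probe sets agreed in SLC16A6, TAGLN and SLC16A4, with 1 lower each, and in MPP1, with 3 of 15 lower. Those of SLC16A4 ranged from -1.50 to 3.80. In the other genes of the 12 all probe sets were higher. Without the dim filter TAGLN was 1.60-fold, LIPH 1.80-fold and SERPINB9 1.96-fold higher. With the median of rows LIPH was 3.76-fold and MPP1 1.90-fold higher, and with the filter at the 60th percentile MPP1 was 1.80-fold higher.

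Among the genes lower in siNF90 cells, PIGL, an enzyme of glycosylphosphatidylinositol anchor synthesis, had 5.50 ± 0.23 in siNTC and 2.59 ± 0.029 in siNF90 cells (SD, n = 2 each), and all 12 of its probe sets were lower. SULT1E1, the estrogen sulfotransferase, was 6.96-fold lower, with 6.34 ± 0.35 against 3.54 ± 0.50 (SD, n = 2 each). The secreted phospholipase PLA2G2A was 5.70-fold, the amino acid-sensing receptor GPRC6A 4.62-fold, ODAM 4.25-fold and SLCO1B3, a hepatic uptake transporter of organic anions and bile acids, 4.10-fold lower. OLR1, a scavenger receptor for oxidised lipoproteins, was 3.98-fold and CD36, which takes up long-chain fatty acids, 3.37-fold lower. The terminal complement component C7 was 3.80-fold and the transcriptional coactivator EYA3 3.24-fold lower. The acid phosphatase ACPP had 4.19 ± 0.0024 in siNTC and 2.28 ± 0.26 in siNF90 cells, and RNF5, a ubiquitin ligase, 3.26 ± 0.30 and 1.27 ± 0.11 (SD, n = 2 each). No fold is given for PIGL, ACPP, RNF5 or SLC16A4, because the lower of their group means lies below the median of all probe sets on each array. The 7 probe sets of RNF5 carried 1 set of values repeated. The main limma test gave each of them an adjusted p of 0.514. With the trend and robust prior 10 of the 12 passed the threshold, the exceptions being ACPP and RNF5 (adjusted p = 0.064 and 0.13). The adjusted p was 0.0038 for ODAM, 0.0066 for PIGL, 0.0085 for SULT1E1 and between 0.0086 and 0.043 for the others that passed. Without the dim filter CD36 was 1.94-fold, OLR1 2.40-fold, SLCO1B3 2.49-fold and GPRC6A 2.61-fold lower, while with the filter at the 60th percentile SLCO1B3 was 6.46-fold and GPRC6A 7.01-fold lower. With the median of rows GPRC6A was 7.45-fold and PLA2G2A 9.56-fold lower. In ACPP, CD36, PLA2G2A, SLCO1B3, EYA3 and GPRC6A 1 probe set each was higher, by 1.01 in ACPP and 1.18 in CD36. In the other genes of the 12 all probe sets were lower.

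**Figure D1:**
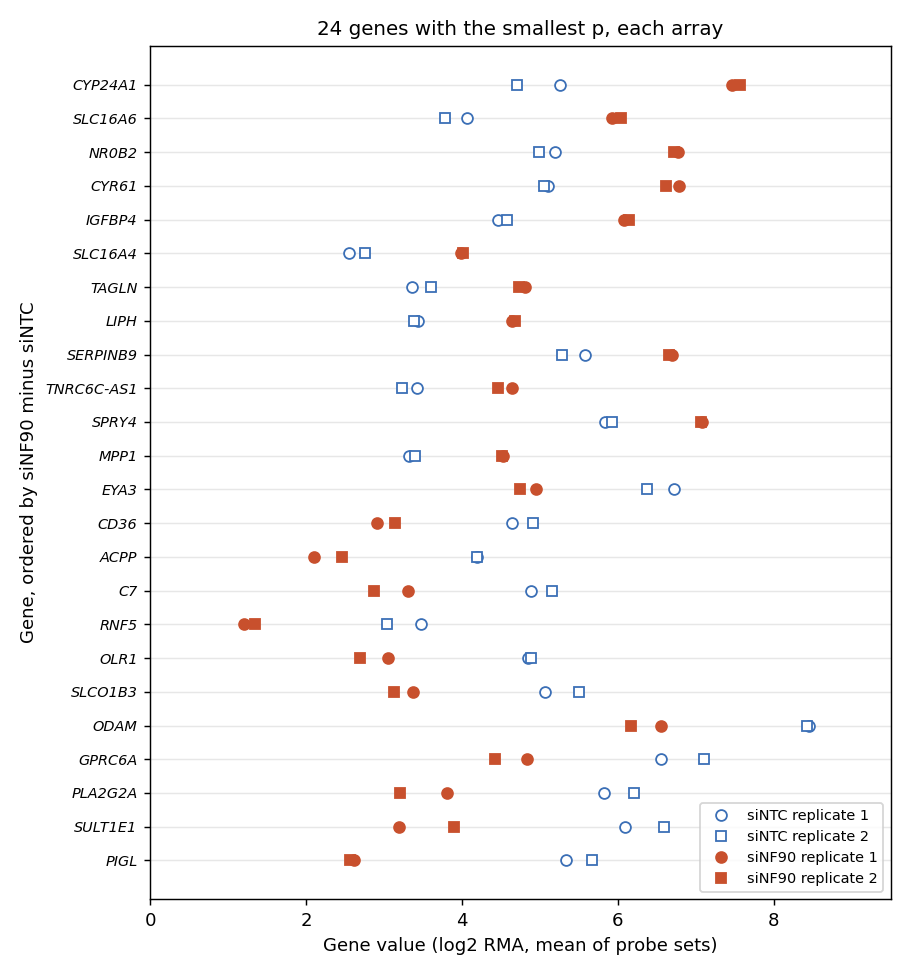
Gene values on the log2 RMA scale (x axis) of the 24 genes with the smallest p, 12 in each direction, ordered by siNF90 minus siNTC. Open blue symbols are the 2 siNTC arrays and filled orange symbols the 2 siNF90 arrays; for each gene the groups do not overlap, by the rule that chose them, as in CYP24A1, with group means of 4.98 and 7.52.

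Of the 35 gene lists, 4 passed the camera test with the preset correlation, 3 higher and 1 lower in siNF90, against 0 in each of the other 2 splits of the arrays. With an estimated correlation 0 of the 35 passed, and 0 passed by fry. That camera test used the few residual degrees of freedom of 4 arrays, and each of the 35 lists had an adjusted p of 0.93. The genes of G2/M and mitosis rose together relative to other genes, by a mean of 0.27 over 31 genes (SD over genes 0.22). Of them 27 had positive differences, and in 17 both siNF90 arrays lay above both siNTC arrays against 0 in the opposite direction. The 2 members with the smallest p were CENPF, a kinetochore protein, at 0.65 (SE 0.23), and CCNB2, cyclin B2, at 0.60 (SE 0.22). PRC1, a cytokinesis factor, had 0.58 (SE 0.22) and the mitotic kinase PLK1 0.40 (SE 0.17). Single members did not pass the threshold, 0 over all genes and 0 adjusted over the list alone. The list had a camera adjusted p of 4.9e-05, and adjusted p = 0.93 with an estimated correlation. The list's median exceeded that of all 10000 random lists matched on level. Those lists lack the correlation among a list's own members, estimated at 0.40 here, so the rank and the counts of members overstate the support. The list's mean also differed by -0.24 between the second and the first siNTC array, close in size to the difference between the groups. Without the first siNF90, second siNF90 or first siNTC array the list still passed, and without the second siNTC array its mean fell to 0.15 with an adjusted p of 0.035. The 34 DNA replication genes had a mean difference of 0.014 and did not pass (adjusted p = 0.768), with a median of -0.0012.

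Genes that report MAPK signalling output rose as a list, by a mean of 0.30 over 21 genes (SD over genes 0.50). Of these, 15 had positive differences, 3 passed when adjusted over the list alone and 0 over all genes tested. The 3 were SPRY4 at 1.19 (SE 0.17), IER3, an immediate early gene, at 1.21 (SE 0.20), and the ERK phosphatase DUSP5 at 1.04 (SE 0.19). SPRY1, another feedback inhibitor, had 0.51 (SE 0.17). MYC had a negative difference of -0.59 (SE 0.20). The camera adjusted p was 0.012, and adjusted p = 0.93 with an estimated correlation. The call was lost without the first siNTC array (mean 0.21, adjusted p = 0.318) and without the first or second siNF90 array (adjusted p = 0.081 and 0.058).

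The NF-kB and inflammatory list rose by a mean of 0.20 over 21 genes (SD over genes 0.48), with a camera adjusted p of 0.043 and adjusted p = 0.93 with an estimated correlation. Of its members 15 had positive differences, 0 passed over all genes and 1, IER3, passed adjusted over the list alone. ICAM1, an adhesion molecule, had 0.86 (SE 0.18) and the colony-stimulating factor CSF1 0.61 (SE 0.20), whereas the apoptosis inhibitor BIRC3 had -1.03 (SE 0.23). IER3 belongs to both this and the MAPK list. Without it the NF-kB list had an adjusted p of 0.135 and the MAPK list 0.042. The NF-kB call was lost under most other settings, among them without the first siNTC array (adjusted p = 0.254), the first siNF90 array (mean 0.10, 0.263) or the second siNF90 array (0.060).

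Acute phase, complement and coagulation genes, the secreted plasma proteins of hepatocytes, fell as a list by a mean of 0.25 over 41 genes (SD over genes 0.44). Of them 27 had negative differences, and in 19 both siNF90 arrays lay below both siNTC arrays against 7 above. C6, a terminal complement component, at -1.33 (SE 0.19) was the 1 member that passed adjusted over the list alone, and 0 passed over all genes. ITIH4, of the inter-alpha-trypsin inhibitor family, had -1.49 (SE 0.32) and the acute phase protein SAA1 -0.71 (SE 0.17), each from 1 probe set. ITIH1 had -0.83 (SE 0.19) and plasminogen (PLG) -0.77 (SE 0.17), while coagulation factor F5 had 0.51. The camera adjusted p was 0.012, and adjusted p = 0.93 with an estimated correlation. The mean stayed between -0.27 and -0.24 when each array was left out. The call was lost without the first siNTC array (adjusted p = 0.074) and without the first siNF90 array (0.193), and with the filter at the 60th percentile (0.064). The 37 hepatocyte differentiation genes had a mean of -0.080 and did not pass (adjusted p = 0.693), although their median of -0.13 lay at percentile 0.61 of the random lists. CPS1, the first enzyme of the urea cycle, had -0.76 (SE 0.18) and ARG1, its last, 0.71 (SE 0.19).

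**Figure D2:**
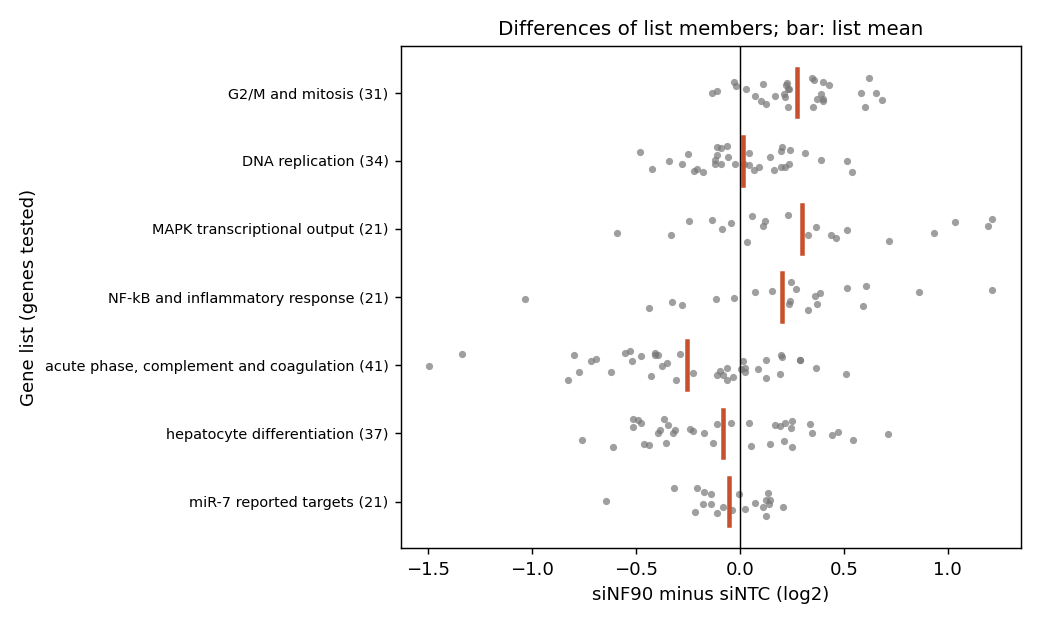
Differences siNF90 minus siNTC on the log2 scale (x axis) of each tested gene (grey points, spread vertically at random) in 7 of the 35 lists, with the list mean as an orange bar and the number of genes in parentheses. The mitosis genes have a mean of 0.27 and the acute phase, complement and coagulation genes one of -0.25, while the DNA replication genes centre on 0.014.

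The lists nearest to the question of miR-7 did not pass. The 21 reported miR-7 targets had a mean difference of -0.054 (SD over genes 0.20, adjusted p = 0.768). Of these, 9 were positive and 12 negative, and XRCC2, a DNA repair gene, at -0.64 (SE 0.21), and IRS1, an adaptor of the insulin receptor, at -0.31 (SE 0.20), had the smallest p. The genes of EGFR, RAS, MAPK and PI3K signalling had a mean of 0.043 (22 genes, adjusted p = 0.693), with MAP2K2 at 0.57 (SE 0.21) and PLCG1 at 0.35 (SE 0.17). Proteins that bind double-stranded RNA or process microRNAs had a mean of -0.048 (23 genes, adjusted p = 0.768). Among them ZFR, which is related to NF90, had 0.50 (SE 0.21) and TNRC6B, a partner of Argonaute proteins, -0.47 (SE 0.23). The interferon response genes had a mean of -0.12 (37 genes, adjusted p = 0.464), with PARP9 at -0.75 (SE 0.18) and the RNA sensor IFIH1 at -0.66 (SE 0.17). The G1/S list had a mean of -0.0095 (24 genes, adjusted p = 0.876), with the licensing factor CDT1 at 0.57 (SE 0.17) and CDC6 at -0.49 (SE 0.22). For p53 targets the mean was -0.041 (24 genes, adjusted p = 0.768) and for apoptosis regulators -0.10 (23 genes, adjusted p = 0.693).

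The other lists did not pass either. Extracellular matrix and mesenchymal genes came closest, with a mean of 0.15 over 30 genes (adjusted p = 0.129). Their 1 member that passed adjusted over the list alone was CYR61, and the integrin subunit ITGAV had 0.89 (SE 0.19). This list did pass with a variance trend in camera (adjusted p = 0.019) and with the median of rows (0.023). The robust prior was not used for lists. With an estimated correlation, run only in the main setting, the adjusted p of the matrix list was 0.93. Splicing factors and hnRNPs had a mean of 0.10 (adjusted p = 0.297), which was 0.034 without the second siNTC array. With the median of rows this list passed (mean 0.20, adjusted p = 0.025). Its adjusted p with an estimated correlation in the main setting was 0.93. The mean was -0.18 for WNT pathway targets (adjusted p = 0.450), and hypoxia targets had 0.10 (0.459), TGF-beta and SMAD targets 0.073 (0.482), glycolysis genes 0.063 (0.482), cholesterol synthesis genes -0.10 (0.482) and replication-dependent histones 0.089 (0.482). An adjusted p of 0.693 applied to NRF2 targets (mean -0.066), heat shock proteins (-0.086) and fatty acid oxidation genes (-0.060). An adjusted p of 0.768 applied to oxidative phosphorylation (mean 0.023), lysosome and autophagy (0.019), the unfolded protein response (-0.051) and ribosome biogenesis (-0.050). Ribosomal proteins had a mean of -0.00085 (adjusted p = 0.853), fetal and progenitor liver genes 0.011 (0.868), and the ATF4 stress response -0.025, aminoacyl-tRNA synthetases -0.0012 and fatty acid synthesis genes -0.039 (each 0.876). The mean and the direction of the test differed in sign for G1/S, ATF4, ribosomal protein and aminoacyl-tRNA synthetase genes, and the median and the mean for DNA replication, G1/S, ribosomal protein and fatty acid synthesis genes. Markers of other cell types did not pass, with means of 0.090 for 14 stromal and endothelial markers (adjusted p = 0.482, median 0.27 at percentile 99.5 of the random lists) and 0.15 for 13 immune markers (adjusted p = 0.768).

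Within genes, single probe sets were compared because a gene mean can hide a change in part of a transcript. Of 171120 probe sets, limma called 0, with 12629 at an unadjusted p under 0.05 and 11 calls with the trend and robust prior. The diffSplice test called 446 of 16175 genes as having probe sets that changed unequally. The other 2 splits of the arrays gave 192 and 246 such genes, and a test on each probe set's own spread gave 0 in all 3 splits, but called 0 of 50 changed genes in simulated data at the spread of these arrays. The diffSplice count was 800 without the first siNF90 array, 132 without the second and 196 without the second siNTC array. On simulated data diffSplice called 1839 unchanged genes. The 5 genes with the smallest false discovery rate were CTSA, FLOT1, MED23, PIGT and PROC. In MED23, a Mediator subunit, the probe sets ranged from -0.41 to 4.51 around a median of 0.16, and in CTSA, the lysosomal cathepsin A, from -1.64 to 3.25 around 0.22. PIGT, of the glycosylphosphatidylinositol transamidase, ranged from -2.92 to 0.77 around 0.37. PROC, which encodes protein C, ranged from -0.33 to 2.61 around -0.14. FLOT1 ranged from -0.65 to 2.19, but its 124 probe sets held only 31 different sets of values.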

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

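Tests chosen after seeing the data were those on genes with at least 3 rows, on identical rows counted once, with the trend on the mean level removed and on each row's own spread. The main limma test called 0 genes, and 0 at least 2-fold, under every setting run except 2: no dim filter (4 genes, all 4 at least 2-fold: PIGL, CYP24A1, SULT1E1 and CYB561A3) and the trend and robust prior (48 genes, 34 at least 2-fold, and 11 probe sets). EGFR kept its sign and missed the threshold under all of them. Over all genes the replicate numbers showed no pairing of the arrays. For DNA replication genes the second minus the first array was -0.27 in siNTC and -0.13 in siNF90. For extracellular matrix genes it was 0.15 and -0.088. A replicate effect shared by some genes is therefore not excluded. With the replicate block 0 genes and 0 probe sets were called, and 287 genes had unequal probe sets. In camera 1 list call was lost, that of the NF-kB list (mean 0.20, adjusted p = 0.069). Where 1 array is left out, the lone array is assumed to vary like the other group. Then between 1 and 5 lists passed and between 132 and 800 genes had unequal probe sets. Both extremes of the unequal count came from siNF90, 800 without the first and 132 without the second array, with 196 without the second siNTC array, and the mean differences ranged as follows: MAPK 0.21 to 0.39, NF-kB 0.10 to 0.30, acute phase -0.27 to -0.24, extracellular matrix 0.079 to 0.23, G1/S -0.041 to 0.022, p53 -0.12 to 0.040, fetal liver -0.012 to 0.034, ribosomal proteins -0.0042 to 0.0025, ribosome biogenesis -0.14 to 0.040, lysosome -0.0036 to 0.042, DNA replication -0.12 to 0.15, ATF4 -0.10 to 0.049, aminoacyl-tRNA synthetases -0.033 to 0.030, oxidative phosphorylation -0.038 to 0.085, histones -0.075 to 0.25, NRF2 -0.17 to 0.036, EGFR and RAS signalling -0.0015 to 0.088, fatty acid synthesis -0.12 to 0.043, interferon -0.22 to -0.014, glycolysis 0.012 to 0.11, splicing factors 0.034 to 0.17, fatty acid oxidation -0.11 to -0.0098, heat shock proteins -0.15 to -0.025, unfolded protein response -0.10 to -0.0033, cholesterol -0.15 to -0.057, miR-7 targets -0.078 to -0.029, double-stranded RNA and microRNA processing -0.071 to -0.026, apoptosis -0.12 to -0.079, hypoxia 0.076 to 0.13, WNT -0.23 to -0.13, immune markers 0.10 to 0.21, hepatocyte differentiation -0.14 to -0.020, stromal markers 0.00074 to 0.18, TGF-beta 0.0057 to 0.14, mitosis 0.15 to 0.39, EGFR itself 0.046 to 0.25, CCNE1 -0.42 to 0.20 and ILF2 -0.12 to 0.028. The matrix list passed without the second siNTC array. With an estimated correlation, and with fry, 0 lists passed, the means being the same (mitosis 0.27, MAPK 0.30, NF-kB 0.20, acute phase -0.25); fry, which tests whether the genes of a list move one way and does not compare them with other genes, gave adjusted p = 0.512 for the first 3 and 0.292 for the last. The filter at the 60th percentile left 2 lists, ending the NF-kB (0.15) and acute phase (-0.23, adjusted p = 0.064) calls, and turned EGFR and RAS signalling to -0.0099, p53 to 0.00069, NRF2 to 0.019 and ILF2 to 0.094. The median of rows ended the NF-kB call (0.14), added splicing factors (0.20) and the matrix list (0.24), and turned p53 to 0.0065, the lysosome to -0.023 and ILF2 to 0.20. No dim filter ended the NF-kB call (0.13) and turned ILF2 to 0.0055. Requiring 50% of a gene's rows ended it too (0.19) and turned immune markers to -0.13. Quantile normalization again turned ILF2 to 0.061, aminoacyl-tRNA synthetases to 0.0084 and ribosomal proteins to 0.0085. The variance trend in camera, run for lists in place of the trend and robust prior, added the matrix list (0.15). Genes with at least 3 rows left 2 lists, ending the NF-kB (0.17) and acute phase (-0.21, adjusted p = 0.052) calls, and turned DNA replication to -0.0015, fetal liver to -0.0062, ribosomal proteins to 0.0088 and immune markers to -0.0090. Removing the trend on the mean level turned G1/S to 0.0034, counting identical rows once turned aminoacyl-tRNA synthetases to 0.0026, and the test on each row's own spread gave 0 genes with unequal probe sets, but also called 0 of 50 changed genes in simulated data at this spread. Over all lists and settings, 529 mean differences kept their sign and side of the threshold, 24 lost the call, 4 gained it and 37 changed sign. All of the 24 genes named by smallest p that could be tested kept their sign in each setting with all arrays, but 7 had a fold more than 1.5 times smaller without the dim filter. Settings that change only the test, such as the replicate block, keep the differences by construction and could not change a sign. In the main setting 31 lists had no call to lose, so these counts do not measure robustness. The causes of these changes were not tested. The mitosis list passed under every setting run with the preset correlation. No background signal was analysed here, so dimness was judged from the values alone.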

Other observations

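The tests on the mitosis and acute phase lists were chosen only after their results had been seen. Several of the 48 genes called with the trend and robust prior have not been described so far, and were named after their values were seen. Their SE and adjusted p are those of that fit. The fatty acid genes went both ways: ACLY, which makes cytosolic acetyl-CoA, rose by 0.78 (SE 0.095, adjusted p = 0.018) and GPAM, the first enzyme of triglyceride synthesis, fell by 1.06 (SE 0.16, adjusted p = 0.043). DKK1, a secreted WNT antagonist, fell by 0.84 (SE 0.085, adjusted p = 0.0085). WEE1, the kinase that holds back mitotic entry, fell by 0.80 (SE 0.12, adjusted p = 0.043), and the circadian regulator CLOCK fell by 1.11 (SE 0.13, adjusted p = 0.015). CYP1A1 rose by 0.93 (SE 0.14) and CYP2S1 by 1.36 (SE 0.19), both cytochrome P450 genes that the aryl hydrocarbon receptor induces. In the main test each of these genes missed the threshold.

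The mitosis list was higher in siNF90 cells while the DNA replication list was not. The mean of the mitosis list minus that of the replication list was 0.63 and 0.65 on the siNTC arrays and 0.88 and 0.92 on the siNF90 arrays, a rise of 0.26 whose gap of 0.23 between the groups exceeded the largest range within a group, 0.033. More cycling cells that raise both lists alike would not give that gap. Whether they would raise both alike was not tested, so an unequal rise stays open. A trend of the difference on the mean level is argued against, since the list kept a mean of 0.27 with the trend removed (camera adjusted p = 0.00027). A single low control array stays open: the mean was 0.15 (adjusted p = 0.035) without the second siNTC array, and the gap between the groups in the list's mean per array, 0.11, did not exceed the range within siNTC, 0.24. A longer stay in G2 or M, or a direct effect of NF90 on these mRNAs, may fit, but neither was tested. The list's own significance stays open with the estimated correlation of 0.40 (camera adjusted p = 0.93). All 35 lists had that adjusted p, and the few residual degrees of freedom were the same for each. The acute phase list, with an estimated correlation of 0.0087, went from an unadjusted camera p of 0.0010 to 0.079 with the estimate. The mitosis list went from 1.4e-06 to 0.27 in the same camera tests. Correlation among the mitosis genes therefore weakened this call beyond what the degrees of freedom did.

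The acute phase, complement and coagulation list was lower in siNF90 cells. The trend on the mean level is argued against, with a mean of -0.25 (adjusted p = 0.0056) after its removal, and so is 1 deviating array, since the mean closest to 0 with an array left out was -0.24 and the gap between the groups, 0.24, exceeded the largest range within a group, 0.031. The call itself was lost without the first siNTC array or the first siNF90 array, where fewer arrays were tested. It was lost too with an estimated correlation (camera adjusted p = 0.93) and by fry (adjusted p = 0.292). The estimated correlation was 0.0087, below the preset 0.01, so correlation among these genes does not explain the loss in camera. Whether the whole hepatocyte programme shifted cannot be told apart from a change of plasma protein genes: the difference between this list and the hepatocyte differentiation list fell by 0.17, but the gap between the groups, 0.088, did not exceed the range within a group, 0.090. A biological effect of the depletion may account for the list and was not separated from off-target effects of the siRNA, since only 1 siRNA label is given.

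The 446 genes with unequal probe sets might reflect noise of single probe sets. The highest count in the other splits was 246, which lay between the limits set beforehand for noise and against it, so that test left this open. On simulated data diffSplice called 1839 unchanged genes, more than the 446, so noise alone can give calls in such numbers. The simulation also gave more calls than the other splits, so it does not tell what share of the 446 is noise.

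CYR61, CTGF and ANKRD1, known targets of YAP and TEAD, had differences of 1.62, 0.87 and 0.79. None passed the main test, CYR61 and CTGF passed with the trend and robust prior, and ANKRD1 passed under no setting run. The hypothesis that such targets shift together was tested on 16 others: their mean was 0.093 (SD over genes 0.53), 8 were positive, and camera gave an unadjusted p of 0.301 (0.383 with an estimated correlation), so the test could not decide. AXL had 1.34 (SE 0.23), F3 0.99 (SE 0.17) and MYOF -0.88 (SE 0.28), none past the threshold. NR0B2, a target of the bile acid receptor FXR, was 3.13-fold higher, but the 9 others tested went against the hypothesis that FXR targets rise together. The activity of FXR itself was not tested. All 9 others were lower, with a mean of -0.40 (SD over genes 0.32; unadjusted camera p = 0.0023, and 0.23 with an estimated correlation), none past the threshold by itself, among them SULT2A1 at -1.02 (SE 0.22) and SLC51B at -0.83 (SE 0.23).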
